A study of Mus musculus with 24 samples.

How the data were processed

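RNA sequencing measured gene expression in MPP3, a myeloid-biased population of multipotent blood progenitors, sorted from the bone marrow of transplanted mice. Boy/J recipients received sorted progenitors of Cebpa+/+ (WT) or CebpaΔ/Δ (KO) donors, carrying YFP, together with C57BL/6 competitor bone marrow without YFP. For 20 days the recipients got injections of PBS or of 0.5 µg IL-1β, and YFP-positive (donor) and YFP-negative (competitor) MPP3 were collected apart. This gave 24 libraries in 8 groups of 3. The labels state that total RNA was extracted and made into libraries with a stranded total RNA kit for very low input, sequenced as read pairs, while their molecule field reads polyA RNA, and both statements are given here as they stand. The labels do not say whether the 3 replicates of a group are separate mice, nor whether a replicate number marks a shared mouse, litter or day. If replicates came from 1 mouse, the p-values measure only the spread between these samples, which may be technical.

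Per the submitters' processing notes, the authors used STAR 2.6.0a, limma (no version given) and the mouse build GRCm38.p6. The read counter, annotation and strand setting are not given there. The deposited table holds raw counts, 1 whole number per gene symbol and library, for 55417 symbols, of which 20856 had no count in any library. All of its symbols were found among the 55418 symbols of GENCODE M21, of which 115 belong to more than 1 gene. The deposited limma tables of 5 comparisons hold log2 fold changes, the limma statistic and log-odds as scores, and p-values. They were used only for a side-by-side count, and for Cebpb in KO against WT donor cells under IL-1.

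Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 8 groups, which left 19509 genes tested. TMM factors ranged from 0.895 to 1.07. A quasi-likelihood model with 1 mean per group was fitted to all 24 libraries with robust dispersion, and each gene was tested two-sided with Benjamini-Hochberg (BH) adjustment at 0.05 within each comparison. Counts of genes passing, and every adjusted p of a gene given without another tool's name, come from this edgeR test. The common biological coefficient of variation was 52.4%, with 16 residual and 10.9 prior degrees of freedom. Expression is given as normalised CPM (counts scaled to a library of 1 M), as mean ± SD with n = 3, and fold changes as log2 ± SE from the model. Passing needs a model across genes, since an exact permutation of 3 libraries against 3 cannot go below p = 0.1.

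The 12 comparisons were KO against WT donor cells under PBS and under IL-1, IL-1 against PBS in WT and in KO donor cells, the same 4 contrasts in competitor cells (named by the recipients' donor genotype), and donor against competitor cells within each of the 4 recipient groups. A further contrast, the interaction, tested whether the IL-1 effect differed between KO and WT donor cells. The 3 main comparisons were both KO against WT contrasts in donor cells and IL-1 against PBS in WT donor cells.

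Genes were named by a fixed rule. Cebpa was named throughout, and Cebpb, Cebpd, Cebpe, Cebpg, Spi1, Il1r1 and Il1rap once per main comparison. Next came the genes with the largest log2 fold changes among those passing, with at least 10 CPM in the higher group and no overlap between the libraries of the groups. These were 10 per direction in the main comparisons, 5 per direction in IL-1 against PBS in KO donor cells, in the interaction (without the overlap condition) and in donor against competitor cells of KO recipients, and 3 per direction elsewhere. Predicted or unnamed genes, pseudogenes, and immunoglobulin and T cell receptor segments were passed over. Up to 2 members per direction with the smallest adjusted p completed each list described. From the genes so chosen, the text gives examples that kept adjusted p under 0.05 in every alternative run, unless it says otherwise.

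The lists, 24 in all with 504 memberships, were written from general knowledge of blood cells. They cover granulocyte-monocyte progenitor granule genes, neutrophil maturation, monocyte and dendritic genes, myeloid regulators and cytokine receptors, stem cell genes, megakaryocyte and platelet genes, erythroid genes, lymphoid progenitor genes, mature B cell, T and NK cell, macrophage, basophil and mast cell, eosinophil, and stromal and endothelial markers, G1/S and G2/M cell cycle genes, NF-kB and IL-1 response, interferon response, MHC class II, ribosome biogenesis and MYC-linked genes, mitochondrially encoded genes, immediate early genes and the unfolded protein response. The other list held sex-linked check genes. It had 1 tested member of 5, so it was not tested as a set. The lists were tested with limma 3.58.1's camera, a test of a list against all other genes, on voom values with a preset inter-gene correlation of 0.01, BH-adjusted over 299 tests. Of the 128 calls, 104 were lost when the correlation was estimated from the data, and 24 of the 299 tests passed in that form. For each list, members passing are also counted with BH adjusted over the list alone. Genes called in IL-1 against PBS over the competitor cells of both recipient kinds formed a higher and a lower set, tested in donor cells with fry, a rotation test of whether a set moves on balance in 1 direction, BH-adjusted over its 10 tests.

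Depth is given in M counts (M for mega). A gene with 0 counts in all libraries of a group was given a bound against 3 counts per library. Such bounds cover counting error only, since the counts carry no molecular identifiers. Between replicates, the chi-square per degree of freedom was 21.9 to 91.1, so summed over genes the spread between libraries exceeded the counting error. Abundant genes weigh most in this value, so it does not cover genes with few counts.

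Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors in edgeR, no filter on low counts, a filter of 5 CPM in 3 libraries, a fit of only the groups compared, the replicate number as a block over all libraries or within a recipient group, leaving out each library in turn, and for lists fry, an estimated correlation and the blocked fit. Added after results were seen were fits without the 4 IL-1 libraries numbered 1, and the replicate block with only the groups compared. Whether replicate numbers pair libraries was checked by correlating, over 9128 genes, deviations from the group mean of libraries of the same number. Every such correlation exceeded 0.1 under IL-1 in KO against WT donor cells and in donor against competitor cells of both recipient kinds. The other comparisons fell short of this. Between PBS groups the correlations were 0.053 to 0.21, each the highest for its library, so weaker pairing is possible.

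The pipeline was tested on simulated data with 200 changed genes among 18569 tested, drawn from negative binomial distributions with the means and dispersions of the real libraries. With the KO against WT layout, edgeR recovered 57.1% and 62.5% of genes changed by log2 -2 and 2, and 38.3% and 32.7% of those changed by log2 -1 and 1, and 7.07% of its calls were unchanged genes. For limma-voom this false share was 8.08% and for DESeq2 24.8%, and after this was seen the pass mark of the test was applied to edgeR and limma-voom alone, so DESeq2 counts stand only among the alternatives. For the interaction, edgeR recovered 51.0% and 52.1% at log2 -2 and 2, and 25.5% and 20.4% at log2 -1 and 1, and 4.00% of its calls were unchanged genes. No library was left out of the fit behind the main values.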

Results

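The count table covered 24 MPP3 libraries, 3 in each of 8 groups, with 23.8 to 42.8 M counts per library (median 31.75 M). By group, depth ranged from 31.7 to 33.2 M in WT PBS donor cells, 31.1 to 39.6 M in WT IL-1 donor cells, 29.6 to 36.2 M in KO PBS donor cells and 23.8 to 29.0 M in KO IL-1 donor cells. In competitor cells it was 29.1 to 34.8 and 32.8 to 42.8 M in WT recipients with PBS and IL-1, and 26.8 to 31.8 and 26.2 to 29.7 M in KO recipients. The 6 most abundant genes, ribosomal or mitochondrial RNAs such as Gm23935, mt-Rnr2 and mt-Rnr1, took 20.2% to 24.7% of counts. Mitochondrial messages took 0.793% to 1.35%. All libraries held Xist at 44480 to 112983 counts, and the Y-linked check genes had 0 to 6 counts.

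Cebpa, the transcription factor removed in the KO donors and required for granulocyte-monocyte development, lies on chromosome 7 at 35119293 to 35121928 on the plus strand (GRCm38). Its level was 69.2 ± 18.4 CPM (SD, n = 3) in WT donor cells with PBS and 5.76 ± 2.49 CPM (SD, n = 3) in KO donor cells, 8.32% of the WT level. With IL-1 it was 125 ± 15.4 CPM (SD, n = 3) in WT and 4.0 ± 1.38 CPM (SD, n = 3) in KO donor cells, 3.19% of the WT level. Competitor cells of WT recipients held 66.2 ± 15.1 CPM with PBS and 125 ± 18.8 CPM with IL-1, and those of KO recipients 82.4 ± 11.9 and 104 ± 3.57 CPM (SD, n = 3 each).

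**Figure D1:**
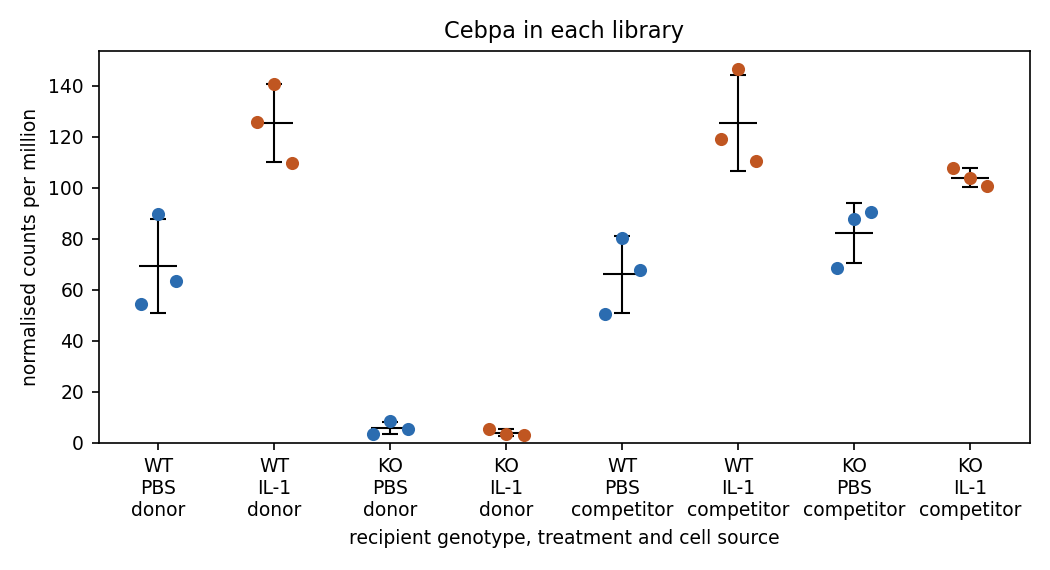
Cebpa in normalised CPM (vertical axis) in each library (points) of the 8 groups (horizontal axis), with the mean and SD of 3 libraries as bars. KO donor cells lay at 5.76 CPM with PBS and 4.0 CPM with IL-1, and the other 6 groups had means between 66.2 and 125 CPM.

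The first comparison asked how loss of Cebpa changed MPP3 without IL-1. In KO donor cells 11 of 20 tested granule genes of early neutrophils and monocytes were lower. Prtn3, a serine protease of neutrophil granules, was at 32.7 ± 6.19 CPM in KO and 186 ± 40.1 CPM in WT donor cells (SD, n = 3 each; log2 -2.51 ± 0.19, adjusted p = 6.81e-09 in edgeR). The granule protease Ctsg (log2 -2.97 ± 0.24, adjusted p = 6.42e-08) and Lbp, which binds bacterial lipopolysaccharide (log2 -3.05 ± 0.21, adjusted p = 7.94e-10), were lower as well. Of 24 lymphoid progenitor genes 4 were higher, 0 lower and 20 did not pass (7 higher and 1 lower adjusted over the list alone). The list's camera call (adjusted p = 5.11e-06) was lost with an estimated correlation (adjusted p = 0.0837). Dntt, which adds nucleotides at antigen receptor junctions, was at 106 ± 36.1 CPM in KO against 17.8 ± 5.85 CPM in WT (SD, n = 3 each; log2 2.57 ± 0.29, adjusted p = 2.54e-06). Tcf7, a transcription factor of the T cell lineage, was higher by log2 2.93 ± 0.34 (adjusted p = 3.84e-06). Scin, which severs actin filaments, had 133 ± 17.8 against 4.07 ± 2.68 CPM (SD, n = 3 each; log2 5.03 ± 0.40, adjusted p = 4.02e-08).

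Of the 20 tested granule genes, 11 were lower in KO cells and 9 did not pass (16 lower when adjusted over the list alone; median log2 -1.51). In camera the list had adjusted p = 2.28e-23, and adjusted p = 0.0484 with an estimated correlation. Of 20 monocyte and dendritic genes, 8 were lower and 12 did not pass (11 lower adjusted over the list alone; median log2 -1.59). Camera gave the list adjusted p = 5.02e-09, and adjusted p = 0.0268 with an estimated correlation. Among its members were Irf8, a factor of monocyte and dendritic fate (log2 -1.83 ± 0.20, adjusted p = 6.78e-07), and F13a1, a subunit of a clotting factor made by monocytes (log2 -3.26 ± 0.49, adjusted p = 0.00103). The myeloid regulators and cytokine receptors had 8 members lower, 1 higher and 18 not passing (12 lower and 1 higher adjusted over the list alone). The camera test of this list gave adjusted p = 7.80e-08, and adjusted p = 0.0133 with an estimated correlation. They included Gfi1, a repressor needed for granulocytes (log2 -2.04 ± 0.20, adjusted p = 2.39e-07), and Csf2rb, the shared receptor chain for GM-CSF, IL-3 and IL-5 (log2 -1.38 ± 0.14, adjusted p = 3.38e-07). Id2, an inhibitor of transcription factors that promotes innate lymphoid fate, was higher (log2 2.54 ± 0.40, adjusted p = 0.000242). Markers of T and NK cells were called higher as well (median log2 0.92, or 1.36 without the 2 members at 0 counts in a group; camera adjusted p = 0.0268, adjusted p = 0.139 with an estimated correlation). Of these 15 markers 2 passed, Lat (log2 1.36, adjusted p = 0.00208) and Lck (log2 1.59, adjusted p = 0.00482), and the call was lost without WT PBS donor libraries 2 and 3 (adjusted p = 0.0897 and 0.269) and KO PBS donor libraries 1 and 3 (adjusted p = 0.14 and 0.119). The neutrophil maturation list had 3 members lower of 18 (6 adjusted over the list alone; 1 without WT PBS donor library 3 or KO PBS donor library 1), such as Pglyrp1, an antibacterial granule protein (log2 -2.05 ± 0.36, adjusted p = 0.00117). That list had a camera adjusted p = 0.00113, and adjusted p = 0.252 with an estimated correlation. Camera also called the G2/M list lower with 0 members passing (adjusted p = 1.65e-05, adjusted p = 0.488 with an estimated correlation) and the unfolded protein response list lower with 1 of 22, Calr (adjusted p = 0.00538, adjusted p = 0.576 with an estimated correlation). The erythroid list was called higher with 2 of 25 passing, Car2 and the globin Hbb-bt (adjusted p = 0.00725, adjusted p = 0.513 with an estimated correlation), a call lost without WT PBS donor library 1 or KO PBS donor library 1 (adjusted p = 0.103 and 0.135); 1 member passed without either of these or without WT PBS donor library 2. The interferon list was called higher with 1 of 30 passing, Usp18 (adjusted p = 0.00378, adjusted p = 0.274 with an estimated correlation), a call lost without KO PBS donor library 1 (adjusted p = 0.0685), and 0 passed without that library or WT PBS donor libraries 2 or 3. The ribosome list was called lower with 0 passing (adjusted p = 0.0364, adjusted p = 0.869 with an estimated correlation), a call lost without WT PBS donor library 2 (adjusted p = 0.266) or KO PBS donor libraries 1 or 3 (adjusted p = 0.0519 and 0.151). The eosinophil (adjusted p = 0.745), mature B cell (adjusted p = 0.263) and stromal and endothelial markers (adjusted p = 0.934) were not called, and had 0, 1 and 0 members passing.

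Among the relatives of Cebpa, Cebpd was lower (log2 -2.26 ± 0.31, adjusted p = 3.39e-05) and Cebpg higher (log2 1.03 ± 0.12, adjusted p = 3.92e-06). Cebpg lies close to Cebpa on chromosome 7, at 35046422 to 35056573. Whether the altered Cebpa locus itself bears on Cebpg, here or with IL-1, was not tested. Cebpe had log2 -1.76 (adjusted p = 0.212), Cebpb log2 -0.09 (adjusted p = 0.892), Spi1 log2 -0.42 (adjusted p = 0.0942), and the receptor genes Il1r1 and Il1rap had log2 0.20 and -0.40 (adjusted p = 0.815 and 0.492). Cebpa itself fell by 3.58 ± 0.26 on the log2 scale (adjusted p = 5.62e-09). Over all 19509 genes, 157 were higher and 262 lower in edgeR (71 and 141 by over 2-fold). Of these 419, 416 had no overlap between libraries, which the test favours. The count was 224 and 267 without WT PBS donor libraries 2 and 3, and 253 and 256 without KO PBS donor libraries 1 and 3. DESeq2 gave 710 genes and the fit with no filter on low counts 718. It was 253 higher and 249 lower in limma-voom, and 275 and 306 with only these groups in the fit.

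Under IL-1, 14 of 20 granule genes were lower and 9 of 24 lymphoid progenitor genes higher in KO cells, and more genes passed than with PBS. Both list calls were lost with an estimated correlation (adjusted p = 0.0743 and 0.0726). Prtn3 was at 45.7 ± 11.3 CPM in KO and 376 ± 65.8 CPM in WT donor cells (SD, n = 3 each; log2 -3.04 ± 0.20, adjusted p = 7.89e-11 in edgeR). Elane, the neutrophil elastase, was at 16.4 ± 8.90 and 336 ± 108 CPM (SD, n = 3 each; log2 -4.37 ± 0.65, adjusted p = 0.000242). Lcn2, an iron-withholding antibacterial protein, was at 1.35 ± 0.554 against 41.0 ± 2.77 CPM (SD, n = 3 each; log2 -4.92 ± 0.75, adjusted p = 0.000197). On the other side, Mycn, a MYC family factor of stem and progenitor cells, was at 74.7 ± 10 CPM in KO and 2.74 ± 1.59 CPM in WT cells (SD, n = 3 each; log2 4.76 ± 0.41, adjusted p = 3.28e-08). Scin rose by log2 6.09 ± 0.42 (adjusted p = 1.33e-09), Dntt by log2 3.43 ± 0.30 (adjusted p = 1.43e-08) and the mast cell protease Cpa3 by log2 3.61 ± 0.30 (adjusted p = 7.03e-08).

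The granule list had 14 members lower, 0 higher and 6 not passing (14 lower and 1 higher adjusted over the list alone; median log2 -2.42). Camera gave the granule list adjusted p = 1.29e-18, and adjusted p = 0.0743 with an estimated correlation. The monocyte and dendritic list had 11 lower and 9 not passing (13 lower adjusted over the list alone; median log2 -1.69, or -1.62 with the member at 0 counts held at its bound). In camera the list had adjusted p = 1.23e-09, and adjusted p = 0.0255 with an estimated correlation. Its members Irf8 (log2 -2.65 ± 0.20, adjusted p = 5.32e-10) and Ccr2, a receptor that guides monocytes from the marrow (log2 -2.15 ± 0.22, adjusted p = 1.12e-07), were lower. Of 27 myeloid regulators, 13 were lower, 1 higher and 13 did not pass (16 lower and 1 higher adjusted over the list alone). Camera gave the list adjusted p = 8.72e-09, and adjusted p = 0.0127 with an estimated correlation. Chaperones and folding enzymes of the endoplasmic reticulum were lower together, with 17 of 22 unfolded protein response genes lower, 0 higher and 5 not passing (18 lower adjusted over the list alone; median log2 -0.996). The camera test of this list gave adjusted p = 1.40e-22, and adjusted p = 0.0255 with an estimated correlation. Calr, a calcium-binding chaperone, was at 992 ± 111 against 2930 ± 451 CPM (SD, n = 3 each; log2 -1.56 ± 0.14, adjusted p = 1.48e-08). The neutrophil maturation list had 5 lower and 13 not passing (5 adjusted over the list alone). Tested with camera, these genes had adjusted p = 0.00239 (0.0535 without KO IL-1 donor library 1), and adjusted p = 0.28 with an estimated correlation.

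Camera called the lymphoid, T and NK cell, platelet and red cell lists higher. Of 24 lymphoid progenitor genes 9 were higher and 15 did not pass (10 higher adjusted over the list alone). As a list they had a camera adjusted p = 1.44e-06, and adjusted p = 0.0726 with an estimated correlation. They included Sox4, a factor of early lymphoid and progenitor cells (log2 1.24 ± 0.11, adjusted p = 5.68e-09). The T and NK cell markers had 2 higher and 13 not passing (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00254, adjusted p = 0.0574 with an estimated correlation), the T cell receptor signalling genes Lat (log2 2.55 ± 0.27, adjusted p = 1.50e-07) and Lck (log2 1.77 ± 0.33, adjusted p = 0.000509). The megakaryocyte and platelet list had 6 higher, 2 lower and 13 not passing (9 and 2 adjusted over the list alone; 3 higher without WT IL-1 donor library 1). In camera the list had adjusted p = 0.00232, and adjusted p = 0.201 with an estimated correlation. The erythroid list had 3 higher and 22 not passing (4 adjusted over the list alone). Camera gave the list adjusted p = 0.00962, and adjusted p = 0.531 with an estimated correlation. Examples were Hemgn, a nuclear protein of blood progenitors (log2 2.19 ± 0.17, adjusted p = 1.08e-09), and the carbonic anhydrase Car2 (log2 1.53 ± 0.11, adjusted p = 3.55e-10). The stromal and endothelial markers were called higher (median log2 1.66, or 1.56 with the 3 members at 0 counts at their bounds; camera adjusted p = 0.0265, adjusted p = 0.102 with an estimated correlation). Of these 10 markers 2 passed, Stab2, a scavenger receptor of sinusoidal endothelium, and Pdgfrb, a growth factor receptor of mesenchymal cells (log2 1.86, adjusted p = 1.95e-06). That call was lost without WT IL-1 donor library 1 or KO IL-1 donor library 3 (adjusted p = 0.144 and 0.0686), and without the 4 IL-1 libraries numbered 1 (median log2 1.02, adjusted p = 0.125). Camera called the stem cell list higher with 5 members higher and 2 lower of 33 (adjusted p = 0.0485, adjusted p = 0.57 with an estimated correlation), a call lost without WT IL-1 donor libraries 1 or 2 or KO IL-1 donor library 3 (adjusted p = 0.0982, 0.139 and 0.123). In any fit without 1 library other than WT IL-1 donor library 2, 1 stem cell gene was lower. The interferon list was called higher with 3 higher and 1 lower of 30 (median log2 0.26, adjusted p = 0.0213, adjusted p = 0.416 with an estimated correlation), a call lost without WT IL-1 donor library 1 or KO IL-1 donor library 1 (adjusted p = 0.181 and 0.0749) and without the 4 IL-1 libraries numbered 1 (median log2 0.09, adjusted p = 0.341). Immediate early genes were called higher with 0 passing (adjusted p = 0.0435, adjusted p = 0.822 with an estimated correlation), a call lost without WT IL-1 donor libraries 1 or 2 or KO IL-1 donor library 3 (adjusted p = 0.191, 0.136 and 0.24), and without the 4 libraries numbered 1 (adjusted p = 0.0529). Not called, with adjusted p in brackets, were the mature B cell (0.491), macrophage (0.828), basophil and mast cell (0.491), eosinophil (0.853), NF-kB and IL-1 response (0.947), MHC class II (0.287) and mitochondrially encoded (0.467) lists. Camera's direction and the median had opposite signs in the mature B cell, eosinophil and NF-kB lists, and the mean and median had opposite signs in the macrophage and NF-kB lists.

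Camera called the cell cycle and ribosome lists lower in KO cells. The G2/M list had 12 of 26 members lower (19 adjusted over the list alone). The camera test of this list gave adjusted p = 1.24e-09, and adjusted p = 0.267 with an estimated correlation. The ribosome biogenesis and MYC-linked list had 5 of 30 lower (15 adjusted over the list alone). Tested with camera, these genes had adjusted p = 1.16e-07, and adjusted p = 0.54 with an estimated correlation. The G1/S list had 4 lower and 0 higher (8 and 1 adjusted over the list alone). As a list they had a camera adjusted p = 9.43e-05, and adjusted p = 0.639 with an estimated correlation. These lists also moved with the replicate number. In each IL-1 group the library numbered 1 stood apart from the other 8 IL-1 libraries, with G1/S genes 0.17 to 0.37, G2/M genes 0.11 to 0.18 and ribosome genes 0.23 to 0.54 above the group mean (log2) and granule genes at -0.41 to -0.27. Without these 4 libraries the 3 lists were still called lower in KO cells (camera adjusted p = 1.27e-05, 4.31e-11 and 6.04e-08 for G1/S, G2/M and ribosome genes). The G2/M list had 5 and 7 members lower without WT IL-1 donor libraries 1 and 2, and 6 and 4 without KO IL-1 donor libraries 2 and 3. The G1/S list had 1 and 10 without WT libraries 1 and 3 and 11, 1 and 2 without KO libraries 1, 2 and 3, and its call was lost without WT library 1 (camera adjusted p = 0.165). The ribosome list had 0 and 10 without WT libraries 1 and 3, and 0 and 1 without KO libraries 2 and 3.

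Under IL-1 Cebpa had log2 -4.96 ± 0.28 (adjusted p = 1.07e-11). Cebpd (log2 -1.42 ± 0.29, adjusted p = 0.00164) and Spi1, the PU.1 factor of myeloid cells (log2 -0.60 ± 0.13, adjusted p = 0.00243), were lower and Cebpg was higher (log2 1.57 ± 0.13, adjusted p = 1.14e-09). Cebpe (log2 -2.97, adjusted p = 0.00484) lost its call in limma-voom (adjusted p = 0.0587, with 4.73e-05 to 0.0419 in its other alternatives). Il1r1 and Il1rap had log2 0.25 and -0.38 (adjusted p = 0.59 and 0.355). In the authors' limma test Cebpb had log2 -0.521 (adjusted p = 0.0291). In edgeR, 849 genes were higher and 1112 lower (338 and 360 by over 2-fold), 1882 of 1961 with no overlap. Of the genes called with PBS, 120 of 157 higher and 211 of 262 lower genes were called the same way with IL-1, against 6.83 and 14.9 for independent calls and 0 called the opposite way. With a replicate block and only these groups in the fit, 2438 genes passed. Without WT IL-1 donor library 1 the count was 1139, and without KO IL-1 donor libraries 2 and 3 it was 1216 and 1262.

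**Figure D2:**
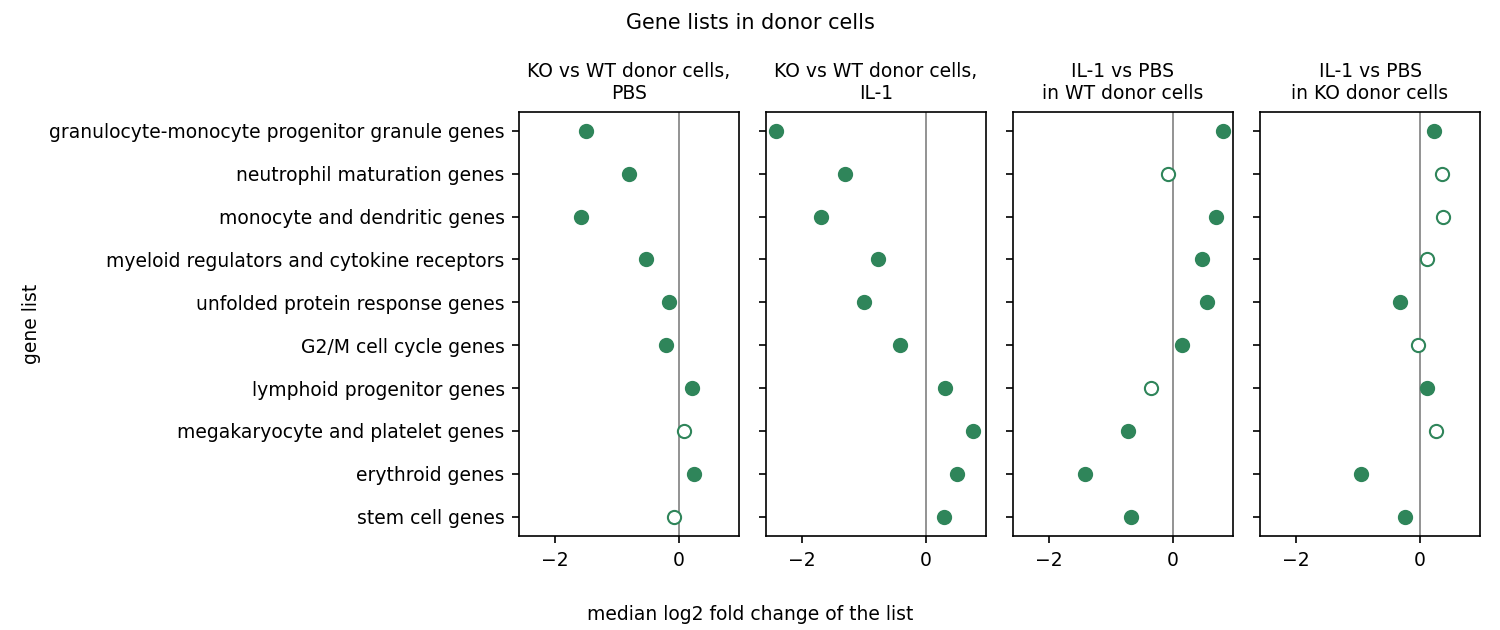
Median log2 fold change (horizontal axis) of 10 gene lists (vertical axis) in 4 comparisons of donor cells (panels), filled where camera gave adjusted p under 0.05 with a preset correlation and open elsewhere. The granule list had medians of -1.51 and -2.42 in KO against WT cells, 0.80 with IL-1 in WT cells and 0.22 with IL-1 in KO cells.

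The third comparison asked what 20 days of IL-1 did to WT donor MPP3. It lowered 8 of 33 stem cell genes (camera adjusted p = 0.0198 with an estimated correlation). Lcn2 rose from 0.471 ± 0.572 to 41.0 ± 2.77 CPM (SD, n = 3 each; log2 6.44 ± 0.82, adjusted p = 0.00024 in edgeR). Ccr2 rose from 13.3 ± 3.55 to 46.4 ± 9.41 CPM (SD, n = 3 each; log2 1.80 ± 0.22, adjusted p = 1.49e-05). Mycn fell from 23.2 ± 1.57 to 2.74 ± 1.59 CPM (SD, n = 3 each; log2 -3.07 ± 0.38, adjusted p = 6.73e-05).

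Of 20 granule genes 6 rose and 14 did not pass (11 adjusted over the list alone; 3 without WT PBS donor library 1; median log2 0.80). In camera the list had adjusted p = 1.95e-12, and adjusted p = 0.147 with an estimated correlation. Prtn3 rose by log2 1.01 ± 0.18 (adjusted p = 0.00274). Among monocyte and dendritic genes 3 rose and 17 did not pass (7 adjusted over the list alone; camera adjusted p = 8.78e-06, adjusted p = 0.0785 with an estimated correlation), Irf8 among them (log2 1.08 ± 0.19, adjusted p = 0.0016). The unfolded protein response list had 11 members higher and 11 not passing (17 adjusted over the list alone; 6 without WT IL-1 donor library 1; median log2 0.55). Camera gave the list adjusted p = 9.11e-16, and adjusted p = 0.0574 with an estimated correlation. Of 33 stem cell genes 8 fell and 25 did not pass (18 lower and 1 higher adjusted over the list alone; median log2 -0.67). The camera test of this list gave adjusted p = 7.21e-15, and adjusted p = 0.0198 with an estimated correlation. Of 25 erythroid genes 5 fell (13 lower and 1 higher adjusted over the list alone; 3 lower without WT PBS donor library 2; median log2 -1.43). Tested with camera, these genes had adjusted p = 2.37e-11, and adjusted p = 0.0658 with an estimated correlation. Those that fell included Car2 (log2 -1.24 ± 0.11, adjusted p = 2.10e-07) and Hemgn (log2 -1.44 ± 0.17, adjusted p = 1.19e-05). Of 21 megakaryocyte and platelet genes 3 fell (5 adjusted over the list alone; 1 without WT PBS donor library 1 or WT IL-1 donor library 2). As a list they had a camera adjusted p = 1.59e-05, and adjusted p = 0.0727 with an estimated correlation.

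The NF-kB and IL-1 response list had 0 of 25 members passing (camera adjusted p = 0.466), and the feedback genes Nfkbia and Nfkbiz had log2 -0.74 and -1.12 (adjusted p = 0.0926 and 0.148). Camera called the immediate early genes lower with 0 passing (1 lower adjusted over the list alone; median log2 -1.39, adjusted p = 5.42e-10, adjusted p = 0.256 with an estimated correlation). The interferon list was called lower, with 2 members lower, 1 higher and 27 not passing (7 lower and 1 higher adjusted over the list alone). In camera the list had adjusted p = 3.28e-05, and adjusted p = 0.106 with an estimated correlation. Myeloid regulators were called higher in camera (adjusted p = 1.75e-06, adjusted p = 0.0198 with an estimated correlation) with 2 of 27 passing (6 adjusted over the list alone; 1 without WT PBS donor library 1 or WT IL-1 donor library 2), and mitochondrially encoded genes were called lower with 1 of 13 passing (adjusted p = 0.00042, adjusted p = 0.28 with an estimated correlation; 0 without WT PBS donor libraries 1 or 2 or WT IL-1 donor libraries 1 or 2). Macrophage markers were called lower with 0 passing (median log2 -0.86, adjusted p = 0.025, adjusted p = 0.321 with an estimated correlation), a call lost without WT PBS donor library 2, WT IL-1 donor libraries 1 or 3 (adjusted p = 0.177, 0.063 and 0.251) or the 4 IL-1 libraries numbered 1 (adjusted p = 0.0861). Stromal and endothelial markers were called lower with 1 of 10 passing, Stab2 (median log2 -1.05, or -0.35 without the 3 members at 0 counts in a group; adjusted p = 0.0057, adjusted p = 0.0559 with an estimated correlation). That call was lost without WT IL-1 donor library 1 (adjusted p = 0.0942) or the 4 IL-1 libraries numbered 1 (median log2 -0.30, adjusted p = 0.0947), and Stab2 did not pass without WT PBS donor library 1 or WT IL-1 donor libraries 1 or 2. The MHC class II list was called lower with 0 passing (median log2 -0.51, adjusted p = 0.0314, adjusted p = 0.256 with an estimated correlation), a call lost without WT PBS donor library 2 or WT IL-1 donor library 1 (adjusted p = 0.255 and 0.0848) or the 4 IL-1 libraries numbered 1 (adjusted p = 0.0947). The G2/M list was called higher with 0 passing (median log2 0.14, adjusted p = 0.0102, adjusted p = 0.758 with an estimated correlation), a call lost without WT PBS donor libraries 2 or 3 (adjusted p = 0.112 and 0.391), WT IL-1 donor libraries 1 or 2 (adjusted p = 0.215 and 0.0823) or the 4 IL-1 libraries numbered 1 (adjusted p = 0.242). The G1/S and ribosome lists were not called (camera adjusted p = 0.14 and 0.524), and without the 4 IL-1 libraries numbered 1 both were called lower (adjusted p = 0.0362 and 8.32e-08). Without WT IL-1 donor library 1 the ribosome list was called lower (adjusted p = 0.000291), and without libraries 2 and 3 it was called higher (adjusted p = 0.0156 and 0.00752), as was the G1/S list (adjusted p = 0.00573 and 0.00297).

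Cebpa had log2 0.86 ± 0.23 (adjusted p = 0.0521), Cebpb 0.39 (adjusted p = 0.226), Cebpd 0.89 (adjusted p = 0.119), Cebpe 0.82 (adjusted p = 0.632), Cebpg 0.26 (adjusted p = 0.355), Spi1 0.28 (adjusted p = 0.32), Il1r1 0.47 (adjusted p = 0.391) and Il1rap 0.01 (adjusted p = 1.0). In edgeR 209 genes rose and 186 fell (54 and 97 by over 2-fold), 392 of 395 with no overlap. Of the 20 largest changes, 12 kept their call whichever library was left out. The count was 160 and 182 without WT PBS donor libraries 1 and 3, and 215 and 170 without WT IL-1 donor libraries 1 and 2. It was 743 in DESeq2, 711 with no filter and 163 with only these groups in the fit.

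In KO donor cells IL-1 lowered 2 of 33 stem cell genes and raised 2 of 16 basophil and mast cell genes and 2 of 24 lymphoid progenitor genes. With an estimated correlation the camera calls of these 3 lists were lost (adjusted p = 0.201, 0.252 and 0.416). Pgr, the progesterone receptor, fell from 31.2 ± 8.39 to 2.47 ± 1.14 CPM (SD, n = 3 each; log2 -3.66 ± 0.48, adjusted p = 0.000188 in edgeR). Mecom, a stem cell transcription factor, fell by 1.16 ± 0.17 on the log2 scale (adjusted p = 0.000846). Ms4a2, the beta chain of the IgE receptor of mast cells and basophils, rose from 4.03 ± 0.873 to 16.2 ± 1.05 CPM (SD, n = 3 each; log2 2.01 ± 0.31, adjusted p = 0.000864), and Satb1, a chromatin organiser of lymphoid cells, rose by log2 1.05 ± 0.16 (adjusted p = 0.000864). Lcn2 was at 0.175 ± 0.151 and 1.35 ± 0.554 CPM (log2 2.96 ± 0.96, adjusted p = 0.244). Cebpa had log2 -0.51 ± 0.27 (adjusted p = 0.524) and Cebpg rose by log2 0.79 ± 0.12 (adjusted p = 0.000864).

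The stem cell list had 2 members lower and 31 not passing (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000153, adjusted p = 0.201 with an estimated correlation). Camera called the erythroid list lower (median log2 -0.96, adjusted p = 7.26e-09, adjusted p = 0.1 with an estimated correlation) with 1 member higher and 1 lower. The unfolded protein response list was called lower with 0 of 22 passing (1 lower adjusted over the list alone; median log2 -0.33). Camera gave the list adjusted p = 0.000153, and adjusted p = 0.416 with an estimated correlation. The granule list had 1 of 20 higher (median log2 0.22, camera adjusted p = 0.0186, adjusted p = 0.758 with an estimated correlation), a call lost without KO PBS donor library 1 (adjusted p = 0.131) and KO IL-1 donor libraries 2 and 3 (adjusted p = 0.0706 and 0.147). The interferon list was called lower with 0 passing (4 lower adjusted over the list alone; adjusted p = 8.73e-06, adjusted p = 0.0935 with an estimated correlation). So was the ribosome list (adjusted p = 1.93e-05, adjusted p = 0.679 with an estimated correlation), while T and NK cell markers were called higher with 0 passing (adjusted p = 0.00106, adjusted p = 0.0471 with an estimated correlation). The basophil and mast cell list had 2 higher (6 adjusted over the list alone). The camera test of this list gave adjusted p = 0.00741, and adjusted p = 0.252 with an estimated correlation. The call was lost without KO PBS donor library 2 or KO IL-1 donor library 1 (adjusted p = 0.0524 and 0.051), and 1 member rose without KO PBS donor library 2 or KO IL-1 donor library 3. The lymphoid progenitor list had 2 higher, Satb1 and Sox4, and 22 not passing (3 adjusted over the list alone; median log2 0.12, camera adjusted p = 0.022, adjusted p = 0.416 with an estimated correlation). That call was lost without KO PBS donor libraries 2 or 3 or KO IL-1 donor library 2 (adjusted p = 0.0546, 0.125 and 0.0635). In edgeR 83 genes rose and 56 fell (41 and 44 by over 2-fold), 138 of 139 with no overlap. The count was 57 and 63 without KO PBS donor libraries 2 and 3, 67 and 55 without KO IL-1 donor libraries 2 and 3, and 315 without the 4 IL-1 libraries numbered 1. It was 292 in DESeq2 and 303 with no filter, and of the 10 largest changes 3 kept their call whichever library was left out.

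The interaction asked directly whether the IL-1 effect differed between KO and WT donor cells. Hemgn fell with IL-1 in WT cells and its effect was higher in KO cells by log2 1.64 ± 0.24 (adjusted p = 0.00173 in edgeR), and the thrombin receptor F2r differed by log2 1.55 ± 0.26 (adjusted p = 0.00843). The membrane protein App, precursor of the amyloid peptide, differed by log2 -1.19 ± 0.20 (adjusted p = 0.00843). These 3 kept their calls whichever library was left out. Car2 (log2 0.93 ± 0.16, adjusted p = 0.00843) and the choline oxidation enzyme Chdh (log2 -1.43 ± 0.24, adjusted p = 0.00843) lost theirs without WT IL-1 donor library 2 (adjusted p = 0.0544 for each). Cebpa had log2 -1.37 ± 0.35 (adjusted p = 0.181). In all, 15 genes were higher and 10 lower, with 1653 at an unadjusted p under 0.05. The count ranged from 4 to 34 with 1 library left out. It was 11, 12 and 9 without WT PBS donor libraries 1, 2 and 3, 9 and 4 without WT IL-1 donor libraries 1 and 2, 7, 8 and 9 without KO PBS donor libraries 1, 2 and 3, and 7 and 12 without KO IL-1 donor libraries 2 and 3. It was 98 in DESeq2, 153 with no filter and 45 with the replicate block.

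Among lists, the unfolded protein response genes had the smallest adjusted p for a difference in IL-1 effect, and were lower in KO cells by a median log2 of -0.77 (camera adjusted p = 9.85e-23, adjusted p = 0.0255 with an estimated correlation), with 5 of 22 members passing (17 adjusted over the list alone). Its members passing were 0, 1 and 1 without WT PBS donor libraries 1, 2 and 3, 0, 0 and 8 without WT IL-1 donor libraries 1, 2 and 3, 1, 0 and 0 without KO PBS donor libraries 1, 2 and 3, and 0 and 1 without KO IL-1 donor libraries 2 and 3, while its camera adjusted p stayed at or below 6.01e-19. The stem cell list (median log2 0.49, camera adjusted p = 0.000128, adjusted p = 0.201 with an estimated correlation) and the megakaryocyte and platelet list (median log2 0.59, or 0.73 without members at 0 counts in a group; camera adjusted p = 1.49e-05, adjusted p = 0.0727 with an estimated correlation) were called higher, with 1 and 0 members passing (3 and 2 adjusted over the list alone).

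A further test used genes called with IL-1 in competitor cells. Under IL-1 these pair with donor libraries (r 0.2 to 0.66 in WT, 0.15 to 0.37 in KO recipients), so the choice was not independent. Of 749 genes raised in competitors, 97.9% rose in WT and 71.6% in KO donor cells, with medians of log2 0.43 and 0.13. The median difference was -0.28 (fry adjusted p = 0.012), or -0.25 and not passing without the 4 IL-1 libraries numbered 1. Of 699 lowered, 96.6% and 74.0% fell, with medians of -0.56 and -0.21, a median difference of 0.33 (fry adjusted p = 0.000578).

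**Figure D3:**
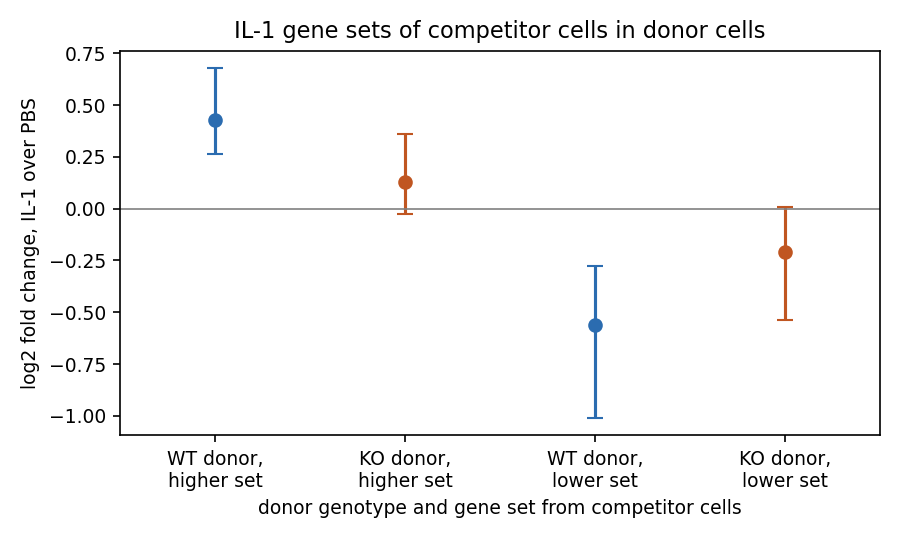
Log2 fold change with IL-1 in donor cells (vertical axis) of the genes that rose (749) or fell (699) with IL-1 in competitor cells, by donor genotype (horizontal axis), with the median over genes as points and the quartiles as bars. The medians were 0.43 and 0.13 for the higher set in WT and KO donor cells, and -0.56 and -0.21 for the lower set.

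**Figure D4:**
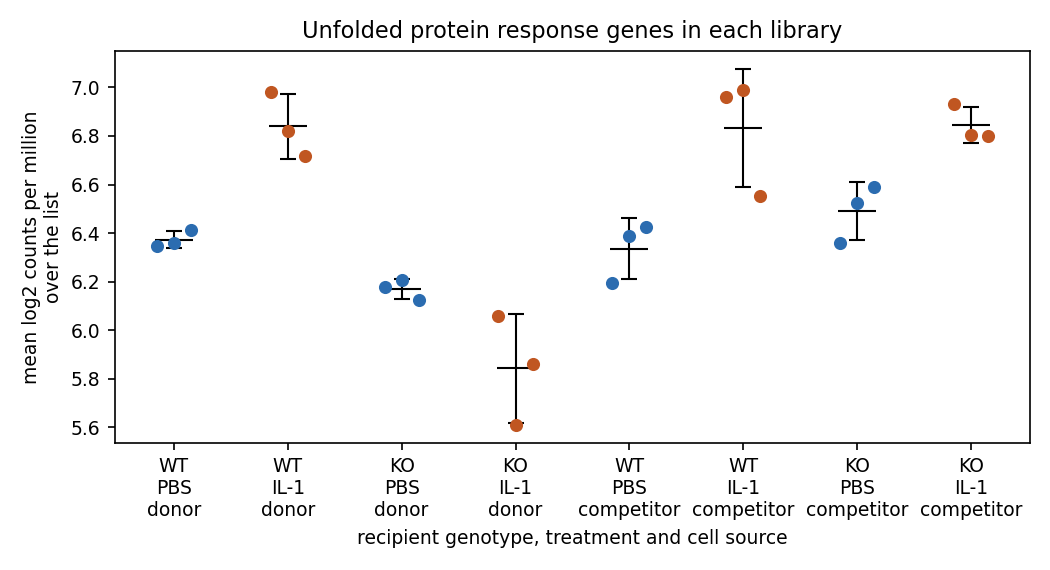
Mean log2 CPM of the 22 tested unfolded protein response genes (vertical axis) in each library (points) of the 8 groups (horizontal axis), with the mean and SD of 3 libraries as bars. KO IL-1 donor libraries lay between 5.61 and 6.06, and WT IL-1 donor libraries between 6.72 and 6.98.

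Competitor cells showed what IL-1 did to cells with normal Cebpa beside either donor. In WT recipients Lcn2 rose from 1.43 ± 0.701 to 39.1 ± 9.36 CPM (SD, n = 3 each; log2 4.76 ± 0.74, adjusted p = 0.00117 in edgeR). Prtn3 rose by log2 1.22 ± 0.18 (adjusted p = 0.000317). Car2 fell by 1.21 ± 0.11 on the log2 scale (adjusted p = 2.75e-07). Of 20 granule genes 7 rose (12 adjusted over the list alone; median log2 0.72, camera adjusted p = 1.08e-14, adjusted p = 0.106 with an estimated correlation). So did 13 of 22 unfolded protein response genes (16 adjusted over the list alone; camera adjusted p = 1.54e-16, adjusted p = 0.0539 with an estimated correlation), and 6 of 33 stem cell genes fell (14 adjusted over the list alone). Tested with camera, the stem cell genes had adjusted p = 4.54e-13, and adjusted p = 0.0255 with an estimated correlation. Leaving out WT PBS competitor library 1 gave 4 granule and 6 folding genes, and WT IL-1 competitor library 2 gave 4 and 7. Without WT PBS competitor library 2 or WT IL-1 competitor library 1, 7 folding genes rose, and without WT IL-1 competitor library 3, 12 stem cell genes fell. Cebpa rose (log2 0.92 ± 0.23, adjusted p = 0.0366), a call lost without WT PBS competitor libraries 1 and 3 (adjusted p = 0.257 and 0.135), WT IL-1 competitor libraries 1 and 2 (adjusted p = 0.0803 and 0.235) and the 4 IL-1 libraries numbered 1 (adjusted p = 0.0947). As in WT donor cells, those 4 libraries bore on the G1/S and ribosome lists, which without them were called lower (adjusted p = 0.0328 and 3.50e-08). In edgeR 190 genes rose and 170 fell, 358 of 360 with no overlap. The count was 141, 236 and 191 without WT PBS competitor libraries 1, 2 and 3, 150 and 703 without WT IL-1 competitor libraries 2 and 3, 657 in DESeq2, 665 with no filter and 126 with only these groups in the fit.

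In competitor cells of KO recipients, Ccr2 rose from 8.65 ± 0.159 to 60.3 ± 12.8 CPM (SD, n = 3 each; log2 2.80 ± 0.23, adjusted p = 1.27e-08 in edgeR) and Lcn2 by log2 4.80 ± 0.74 (adjusted p = 0.000784). Mycn fell from 28.5 ± 10.2 to 3.53 ± 2.67 CPM (SD, n = 3 each; log2 -3.01 ± 0.38, adjusted p = 3.83e-05). Of 20 granule genes 14 rose (16 adjusted over the list alone; median log2 1.41). As a list they had a camera adjusted p = 2.45e-30, and adjusted p = 0.0255 with an estimated correlation. Of 20 monocyte genes 7 rose (11 adjusted over the list alone; camera adjusted p = 7.90e-11, adjusted p = 0.0234 with an estimated correlation), and so did 7 of 22 unfolded protein response genes (15 higher and 1 lower adjusted over the list alone). In camera the folding genes had adjusted p = 8.78e-10, and adjusted p = 0.134 with an estimated correlation. Of 33 stem cell genes 9 fell (14 adjusted over the list alone). Camera gave the list adjusted p = 2.66e-13, and adjusted p = 0.025 with an estimated correlation. Without KO PBS competitor library 1 the granule, monocyte and folding counts were 8, 3 and 4, without KO IL-1 competitor library 3 they were 9, 4 and 4, without KO PBS competitor library 2 the monocyte count was 4, and without KO IL-1 competitor library 2 the folding count was 11. Cebpa had log2 0.34 ± 0.23 (adjusted p = 0.574). Mitochondrial messages took 1.01% to 1.10% of counts with PBS and 1.23% to 1.35% with IL-1, and the mitochondrially encoded list was called higher with 3 of 13 passing (adjusted p = 2.74e-06, adjusted p = 0.139 with an estimated correlation; 0 without KO PBS competitor library 1 and 1 without KO PBS or KO IL-1 competitor library 3). In edgeR 284 genes rose and 322 fell, 597 of 606 with no overlap. The count was 350, 390 and 360 without KO PBS competitor libraries 1, 2 and 3, 274 without KO IL-1 competitor library 3, and 952 in DESeq2. The difference of IL-1 effects between the competitors of KO and WT recipients passed for 0 genes in edgeR. It had 961 genes at an unadjusted p under 0.05, where chance gives 975, and DESeq2 and limma-voom were not run on it.

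Of the genes changed by IL-1 in WT donor cells, 103 of 209 higher and 109 of 186 lower ones were called the same way in competitors of KO recipients, where independent calls would share 3.04 and 3.07. With IL-1 in KO donor cells, a group that shares no library with either, 23 and 21 were shared, against 0.889 and 0.534 for independent calls.

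Competitor cells were also compared between KO and WT recipients, which asks whether the donor genotype altered its neighbours. With PBS 0 genes passed in edgeR (DESeq2 0, limma-voom 0, no filter 18), and with IL-1 0 genes (DESeq2 7, limma-voom 0, no filter 32). In edgeR 726 and 867 genes had an unadjusted p under 0.05, below the 975 that chance gives. Cebpa had log2 0.31 ± 0.23 and -0.27 ± 0.23 (adjusted p = 1.0 for both). With PBS camera called the interferon list higher (median log2 0.24, adjusted p = 1.59e-05, adjusted p = 0.1 with an estimated correlation), with 0 members passing. It also called the unfolded protein response list higher (median log2 0.19, adjusted p = 5.14e-05, adjusted p = 0.371 with an estimated correlation), a call lost without KO PBS competitor library 3 (adjusted p = 0.0584). Granule genes were called lower with PBS (median log2 -0.19, adjusted p = 0.0102, adjusted p = 0.744 with an estimated correlation), a call lost without WT PBS competitor libraries 2 or 3 (adjusted p = 0.698 and 0.138) or KO PBS competitor libraries 1 or 2 (adjusted p = 0.242 and 0.0598). Mature B cell markers were called lower (median log2 -0.91, adjusted p = 0.0381, adjusted p = 0.424 with an estimated correlation), a call lost without WT PBS competitor libraries 1 or 2 (adjusted p = 0.0537 and 0.163) or KO PBS competitor libraries 1 or 3 (adjusted p = 0.0668 and 0.139). So were the eosinophil genes (median log2 -3.60, or -1.52 with the 4 of 8 members at 0 counts at their bounds; adjusted p = 0.000965, adjusted p = 0.0993 with an estimated correlation), a call lost without WT PBS competitor library 2 (adjusted p = 0.0767). None of these 4 lists had a member passing. With IL-1 the granule list (median log2 0.22, adjusted p = 2.09e-06, adjusted p = 0.377 with an estimated correlation) and the mitochondrially encoded list (median log2 0.29, adjusted p = 2.37e-11, adjusted p = 0.0471 with an estimated correlation) were called higher, with 0 members passing (7 mitochondrial genes adjusted over the list alone). The monocyte and dendritic list was called higher with 0 passing (median log2 0.20, mean -0.39, adjusted p = 0.00356, adjusted p = 0.252 with an estimated correlation), a call lost without WT IL-1 competitor library 3 (adjusted p = 0.128).

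Donor and competitor cells of WT recipients, both with intact Cebpa, were compared to find differences that come with the cell source. With PBS 15 genes passed in edgeR (10 higher, 5 lower in donors), and with IL-1 14 (10 and 4), all with no overlap between libraries. The histone gene Hist1h4m was higher in donor cells (log2 3.72 ± 0.25 with PBS, adjusted p = 1.60e-10, and 4.75 ± 0.26 with IL-1, adjusted p = 1.79e-12). Cebpa had log2 0.06 and -0.00 (adjusted p = 1.0 for both). With IL-1, 14 genes passed with the replicate number as a block, 19 with a block within recipient groups and 13 with a block and only these groups in the fit. The count with PBS was 27 with no filter, and with IL-1 it was 28 in DESeq2 and 42 with no filter.

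Donor and competitor cells of KO recipients set cells without and with Cebpa against each other under the same treatment. With PBS Cebpa fell by 3.84 ± 0.27 on the log2 scale (adjusted p = 9.59e-10 in edgeR), Lbp by 3.11 ± 0.21 (adjusted p = 2.67e-10) and Hk3, a hexokinase of myeloid cells, by 2.59 ± 0.22 (adjusted p = 4.43e-08). Scin was higher by log2 4.17 ± 0.38 (adjusted p = 2.56e-07) and Tcf7 by log2 2.17 ± 0.33 (adjusted p = 0.000177). Of 20 granule genes 10 were lower in donors (12 adjusted over the list alone, 6 without KO PBS competitor library 3; camera adjusted p = 2.18e-15, adjusted p = 0.101 with an estimated correlation). So were 8 of 20 monocyte genes (camera adjusted p = 3.76e-07, adjusted p = 0.0484 with an estimated correlation). Camera called T and NK cell markers higher in donors (median log2 1.08, or 0.64 with the 5 members at 0 counts at their bounds; adjusted p = 0.0227, adjusted p = 0.13 with an estimated correlation), a call lost without any 1 of the 6 libraries (adjusted p = 0.0713 to 0.234). In edgeR 153 genes were higher and 268 lower, 420 of 421 with no overlap. The count was 246 and 244 without KO PBS donor libraries 1 and 3, 212 and 220 without KO PBS competitor libraries 2 and 3, 744 in DESeq2, 768 with no filter, 703 with only these groups in the fit, 192 higher and 193 lower in limma-voom, and 1285 with the replicate number as a block within recipient groups.

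With IL-1 Cebpa fell by 4.69 ± 0.28 on the log2 scale (adjusted p = 2.05e-11 in edgeR), Prtn3 by 3.19 ± 0.20 (adjusted p = 3.00e-11), Irf8 by 2.91 ± 0.20 (adjusted p = 7.02e-11) and Calr by 1.57 ± 0.14 (adjusted p = 9.68e-09). Tox, a factor of lymphoid development, was higher by log2 4.81 ± 0.44 (adjusted p = 9.68e-09), Scin by 5.53 ± 0.41 (adjusted p = 3.45e-09) and Dntt by 3.10 ± 0.29 (adjusted p = 4.02e-08). Of 20 granule genes 16 were lower in donors (17 adjusted over the list alone; median log2 -2.67, camera adjusted p = 6.34e-24, adjusted p = 0.0471 with an estimated correlation). So were 18 of 22 unfolded protein response genes (median log2 -0.998, camera adjusted p = 1.09e-22, adjusted p = 0.0255 with an estimated correlation), and 6 of 24 lymphoid progenitor genes were higher. The camera test of this list gave adjusted p = 1.45e-05, and adjusted p = 0.0993 with an estimated correlation. Of 15 T and NK cell markers 3 were higher (median log2 1.80, or 1.69 with the 4 members at 0 counts at their bounds; camera adjusted p = 0.000757, adjusted p = 0.0471 with an estimated correlation). Mitochondrial messages took 1.01% to 1.08% of counts in donors and 1.23% to 1.35% in competitors, and mitochondrially encoded genes were called lower (6 of 13; adjusted p = 0.00052, adjusted p = 0.293 with an estimated correlation). The G2/M list was called lower (14 of 26; adjusted p = 4.33e-10, adjusted p = 0.254 with an estimated correlation), with 6 passing without KO IL-1 donor libraries 2 or 3, and 5 and 8 without competitor libraries 1 and 3. So was the ribosome list (4 of 30; adjusted p = 3.28e-05, adjusted p = 0.689 with an estimated correlation), with 0 passing without KO IL-1 donor libraries 2 or 3 or competitor library 1, 2 without competitor library 3 and 10 without the 4 IL-1 libraries numbered 1. In edgeR 953 genes were higher and 1051 lower, 1961 of 2004 with no overlap. With the replicate number as a block 3072 genes passed with only these groups in the fit and 3275 within recipient groups, and without KO IL-1 competitor library 1 the count was 1317.

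The authors' deposited tables, counted at an adjusted p under 0.05, gave 230 higher and 264 lower genes for KO against WT donor cells with PBS, 1047 and 963 with IL-1, 254 and 301 for IL-1 in WT donor cells, and 0 for competitors of KO against WT recipients with either treatment. Of these, 370, 1740 and 369 were also called in edgeR, all with the same sign.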

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

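The difference between the IL-1 effects in KO and WT donor cells was a planned contrast, while the fits without the 4 IL-1 libraries numbered 1 were tests chosen after results were seen, as was the choice to rest the scaling test on the gap to all genes. Each result in this part drew attention because the IL-1 effect differed between the KO and WT groups in a test of that difference.

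Among genes, the IL-1 effect in KO cells was above that in WT cells for Mycn (log2 2.70), Slc14a1, a urea transporter (log2 1.87), Hemgn (log2 1.64), F2r (log2 1.55), Tjp1, a tight junction protein (log2 1.34), and Car2 (log2 0.927). It was below that in WT cells for the endoplasmic reticulum protein Creld2 (log2 -1.45), Chdh (log2 -1.43), the chaperones Hspa5 (log2 -1.26) and Hyou1 (log2 -1.23), and App (log2 -1.19). Hemgn, F2r and App kept adjusted p under 0.05 without any 1 of the 12 donor libraries. Car2 and Chdh did so except without WT IL-1 donor library 2 (adjusted p = 0.0544 for each). Mycn, Creld2 and Tjp1 lost their calls without any of 10 of the 12 libraries (adjusted p up to 0.119, 0.146 and 0.109), and Hspa5, Hyou1 and Slc14a1 without any of 9 (adjusted p up to 0.118, 0.0993 and 0.165).

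Among lists, with the median difference of IL-1 effects, the stem cell genes (log2 0.491) and the megakaryocyte and platelet genes (log2 0.593) lay higher in KO cells and kept their calls without any 1 library, with adjusted p = 0.201 and 0.0727 with an estimated correlation. Granule genes lay lower (log2 -0.469, camera adjusted p = 0.0135, adjusted p = 0.744 with an estimated correlation), a call lost without WT PBS donor library 1, WT IL-1 donor library 2, KO PBS donor library 3 or KO IL-1 donor library 1 (adjusted p = 0.213, 0.0796, 0.0789 and 0.215). Mature B cell markers lay higher (log2 0.43, camera adjusted p = 0.0372, adjusted p = 0.416 with an estimated correlation), with a median of 1.89 without the 3 of 11 members at 0 counts in a group. Their call was lost without any 1 library (adjusted p = 0.0511 to 0.224) other than WT PBS donor library 3, WT IL-1 donor library 2 or KO PBS donor library 1, and without the 4 IL-1 libraries numbered 1 (adjusted p = 0.0944). Stromal and endothelial markers, of which 4 of 10 were at 0 counts in a group, lay higher (log2 1.08, camera adjusted p = 0.00707, adjusted p = 0.0595 with an estimated correlation), a call lost without WT IL-1 donor library 1 (adjusted p = 0.0671). Without the 4 IL-1 libraries numbered 1 their median turned to -0.0149, while camera still called them higher (adjusted p = 0.0479).

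The G1/S genes (log2 -0.193, adjusted p = 0.772 with an estimated correlation), the G2/M genes (log2 -0.193, adjusted p = 0.689 with an estimated correlation) and the ribosome genes (log2 -0.331, adjusted p = 0.689 with an estimated correlation) lay lower. Without WT IL-1 donor library 1 the calls of all 3 were lost (adjusted p = 0.962, 0.0501 and 0.586), the G1/S call also without KO IL-1 donor libraries 2 and 3 (adjusted p = 0.167 and 0.0571), and the G2/M call also without WT PBS donor library 3 and KO IL-1 donor library 3 (adjusted p = 0.102 and 0.147). Without the 4 IL-1 libraries numbered 1 the G1/S and ribosome medians were -0.0913 and -0.165. Immediate early genes lay higher (log2 0.579, adjusted p = 0.744 with an estimated correlation), a call lost without WT PBS donor library 3, WT IL-1 donor library 1, KO PBS donor library 1 or KO IL-1 donor library 3 (adjusted p = 0.333, 0.0902, 0.274 and 0.0889).

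Genes that rose with IL-1 in competitor cells responded less in KO than in WT donor cells (median difference -0.279, fry adjusted p = 0.012). Without the 4 IL-1 libraries numbered 1 this was -0.253 and no longer passed. Those that fell had a median difference of 0.332 (fry adjusted p = 0.000578).

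The IL-1 effect on unfolded protein response genes was lower in KO than in WT donor cells by a median of -0.766 (adjusted p = 0.0255 with an estimated correlation), with 11 of 22 higher in WT cells (6 without WT IL-1 donor library 1; list adjusted p = 0.0574 with an estimated correlation) and 0 higher in KO cells. The 4 IL-1 libraries numbered 1 are argued against as the cause, since the median was -0.804 without them. A difference in scaling between the genotypes is argued against too, since the list's median lay -0.75 from that of all genes, a gap that a factor per library cannot change. With RLE scaling, which moved little, the list's median was -0.736. A lower load of secretory cargo may explain the pattern. Granule and unfolded protein response genes had r = -0.0756 within groups (permutation p = 0.802, 24 libraries). A prediction set beforehand counts such a p against this cause. It was left open after results were seen, as r had 95% limits of -0.54 to 0.42. Without the 4 IL-1 libraries numbered 1, r was 0.358. A direct role of Cebpa in these genes is open as well, as the biological difference that the design names, and was not tested.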

How the results depend on the processing

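The fits without the 4 IL-1 libraries numbered 1, and the replicate block with only the compared groups, were tests chosen after results were seen, and the other alternatives were set before the data were examined. In the alternatives that kept all replicates or left out those 4 libraries, 87 values of counts and IL-1 sets stayed within 1.5 times of the main value or on their side of the threshold, 27 moved further and 1 weakened. For lists, 478 values stayed, 125 weakened, 14 strengthened and 4 turned direction. For named genes, 4097 stayed, 121 weakened and 153 strengthened. No main call in KO against WT donor cells, or with IL-1 in WT donor cells, was called with the opposite sign in DESeq2, limma-voom, RLE scaling or the stricter filter.

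DESeq2 gave 710 genes for KO against WT donor cells with PBS, 743 and 292 for IL-1 in WT and KO donor cells, 657 and 952 for IL-1 in competitors of WT and KO recipients, 7 between competitors with IL-1, 28 for donor against competitor cells of WT recipients with IL-1, 744 for those of KO recipients with PBS and 98 for the interaction. The fit with no filter on low counts gave, in the same order, 718, 711, 303, 665, 32, 42, 768 and 153, leaving out competitors of KO recipients, and 18 between competitors and 27 for donor against competitor cells of WT recipients, both with PBS. With only the compared groups in the fit, 163, 126 and 703 genes passed for IL-1 in WT donor cells, IL-1 in competitors of WT recipients, and donor against competitor cells of KO recipients with PBS. The replicate block gave 45 genes for the interaction, 1285 and 3275 within recipient groups for donor against competitor cells of KO recipients with PBS and IL-1, and 3072 with only the compared groups for the latter. The cause was not tested for any of these.

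Without the 4 IL-1 libraries numbered 1, 315 genes passed for IL-1 in KO donor cells, and the set raised by IL-1 (difference -0.253) no longer passed. Then the G1/S and ribosome lists, not called with all libraries and with camera's direction then higher, were called lower with IL-1 in WT donor cells (adjusted p = 0.0362 and 8.32e-08) and in competitors of WT recipients (adjusted p = 0.0328 and 3.50e-08). In KO donor cells the G1/S and G2/M lists were newly called lower (adjusted p = 1.14e-08 and 0.00293) and the monocyte and myeloid regulator lists higher (adjusted p = 0.0327 and 0.0414), and in competitors of KO recipients the G1/S and ribosome lists were newly called lower (adjusted p = 0.00175 and 1.56e-08). The cause was not tested.

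With 1 library left out, the counts ranged from 224 to 331 (KO against WT donor cells with PBS), 1139 to 2112 (the same with IL-1), 160 to 355 and 55 to 117 (IL-1 in WT and KO donor cells), 141 to 703 and 274 to 454 (IL-1 in competitors of WT and KO recipients), 212 to 347 and 1317 to 1930 (donor against competitor cells of KO recipients with PBS and IL-1) and 4 to 34 (interaction). Fewer libraries per group lower the power of each such fit. The chi-square per degree of freedom between replicates was 21.9 to 91.1 (about 1 for counting error alone). Abundant genes weigh most in it, so genes with few counts are not covered.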

Other observations

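The tests on the 4 IL-1 libraries numbered 1 and on the genes that part donor from competitor cells were chosen after results were seen, and the counts over other splits of the libraries were not.

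Genes that IL-1 raised in competitor cells were lower in KO than in WT donor cells already with PBS (749 genes, median log2 -0.244, fry adjusted p = 0.000578), and lower still with IL-1 (median log2 -0.537, fry adjusted p = 6.10e-07). Genes that IL-1 lowered were higher in KO cells, with a median log2 of 0.169 with PBS (699 genes, fry adjusted p = 0.0013) and 0.469 with IL-1 (fry adjusted p = 3.66e-07). Over 9128 genes, the fold changes of KO against WT cells with PBS and with IL-1 had a Pearson r across genes of 0.738. Those of IL-1 in WT and KO donor cells had r = 0.362.

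In each of the 4 IL-1 groups, the library numbered 1 deviated from its group in a shared way, with higher G1/S, G2/M and ribosome genes and lower granule genes. Odc1, a polyamine enzyme, was at 324 against a mean of 142 CPM in other WT IL-1 donor libraries, and at 138 against 88.5 CPM in KO ones. A state of single recipient mice stays open, since the r of 0.4 to 0.53 between number 1 libraries of WT and KO recipients restates the pattern, and the states of 1 WT and 1 KO recipient could match by chance. A difference in depth or in the most abundant ribosomal genes is argued against, since 0 of the 2 measures lay on the same side in all 4 groups. A shared day or handling of the animals numbered 1 stays open too, as the labels give no day or batch. Number 1 PBS and IL-1 libraries had r of only -0.2 to 0.046 between them, but shared the lower granule genes. The highest r between unlike numbers, -0.1, decides nothing, as deviations from a group mean sum to 0.

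Donor and competitor cells of WT recipients differed in 12 genes with the same sign under PBS and IL-1, 9 higher and 3 lower in donors. Sequence linked to the Cebpa locus is argued against, since 0 of the 12 lie on chromosome 7. A strain or substrain difference between the donor and competitor mice is a candidate explanation, with 91.7% of these genes called with the same sign in KO recipients under both treatments. Reads shared with near-identical copies could add to it, since 7 of the 12 are pseudogenes or predicted gene models, such as Mid1-ps1, which was at least 33.2-fold higher in donors of WT recipients with PBS. No biological explanation beyond these was tested.

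For groups of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. The real split gave 419 and 1961 genes for KO against WT donor cells with PBS and IL-1, 395 for IL-1 in WT donor cells, 360 and 606 for IL-1 in competitors of WT and KO recipients, 15 for donor against competitor cells of WT recipients with PBS, and 421 and 2004 for those of KO recipients with PBS and IL-1, and the highest of the other splits gave 0 in each, so 1 of 10 splits was as large. For IL-1 in KO donor cells the real split gave 139 and the highest other 2. Between competitors of KO and WT recipients the real split gave 0 genes in edgeR with PBS (DESeq2 0, limma-voom 0) and 0 with IL-1 (DESeq2 7, limma-voom 0). So 10 of 10 splits were as large, with the highest other at 0 and 58. The real splits had 726 and 867 genes at an unadjusted p under 0.05 in edgeR, where chance gives 975.

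For donor against competitor cells of WT recipients with IL-1 the real split gave 14 genes and 2 of 10 splits were as large, the highest other giving 1150, which points to a structure of these libraries. It had both libraries numbered 1 on 1 side, as had 3 other splits, which gave 0, 0 and 1 genes. With a replicate block 14 genes passed, 19 with a block within recipient groups and 13 with a block and only these groups. Where the numbers pair the libraries, in KO against WT donor cells, donor against competitor cells of WT recipients and those of KO recipients, all with IL-1, the 3 other splits that part every pair gave 0 genes each. For the interaction the real split gave 25 genes, 8 of 100 splits were as large and the highest other gave 2622. The other 7 all kept the IL-1 libraries of each genotype together and mixed or swapped the PBS ones, so they hold the difference between the genotypes, and the 92 that mixed the IL-1 libraries gave at most 2 genes with that difference inside their groups. Neither kind shows what a lack of interaction gives, so whether chance can be excluded was left open.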
